A study of Homo sapiens and Mus musculus with 29 samples.

How the data were processed

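The series is built around CETCh-seq, in which CRISPR/Cas9 adds an epitope tag to the gene of a transcription factor at its own locus, so that the protein can be studied with an antibody against the tag. Values were used here for 4 RNA-seq libraries of HepG2, an established human hepatocellular carcinoma line: 2 libraries of unmodified cells, 1 of the RAD21 line and 1 of the ATF1 line. The labels of the last pair name only the cell line and the gene; they were read as lines carrying the tag at that gene, since the series is about tagged factors. The ChIP-seq samples of the series (ATF1, CREB1, GABPA and RAD21 in HepG2, RAD21 in MCF7 and GABPA in mouse embryonic stem cells) were not analysed here. Per the labels' protocols, cells were transfected with FuGENE, selected with the antibiotic G418 and expanded, and polyadenylated RNA was captured on oligo dT beads. The labels call the unmodified libraries biological replicates 1 and 2. The p-values rest on the spread between this pair, except where the modified lines were pooled.

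The authors deposited RPKM values, read numbers scaled to transcript length and to the mapped total of the library, with 1 value per RefSeq transcript and library. The submitters' processing notes name Bowtie, TopHat 1.4.1, bedtools and Cufflinks 1.3.0 and the builds hg19 and mm9, without saying which step or data type each belongs to. Each table held 32062 transcripts of 21453 gene symbols, of which 28652 had a coding and 3410 a noncoding RefSeq identifier. Of these transcripts, 4956 were listed at 0 in every library. Gene names were taken from the tables themselves. The reference table in use was of another assembly, GRCh38.p14, so no coordinates are given, and no genome sequence was used, so GC content was not tested.

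RPKM values keep the depth where whole reads were counted. For each library the total by which the authors had divided was taken from reference genes with 1 transcript under 6000 bp. It was the most common value these genes implied, given by 62 to 73 transcripts per library. The totals were 29661421 and 26270114 mapped reads for unmodified replicates 1 and 2, 24029313 for the RAD21 line and 29972463 for the ATF1 line. The length of a transcript was then the smallest whole number of bp that made each value a whole read number within 0.001. Where reads and true length share a divisor, this length and its reads can come out too small. A length was found for 25692 of the 25692 transcripts above 0 in at least 2 libraries. It was found for 0 of 588 transcripts whose values had each been multiplied by a random factor. The latter shows only that arbitrary values do not give whole reads, not that a length found is the true one. Lengths given here are these computed lengths. For a transcript of 2 kb, an RPKM of 1 was 48.1 to 59.9 reads per library, and a count of 0 allowed at most 0.05 to 0.062 RPKM. Intervals of this kind cover counting error only. Counting error alone did not account for the spread between the unmodified libraries. There 9414 of 11751 genes (80.1%) differed by more than counting allows, at an unadjusted p under 0.05 in a test of proportions. That share does not measure how much of the spread is counting error.

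Because RPKM are not counts, tests were run with limma 3.58.1 in R 4.3.3 on log2(RPKM + 1), over the 18577 transcripts with a mean RPKM of at least 1. Fold changes are on that log2 scale, which understates the change of genes with low values. The design had spoken of genes, and the tables turned out to hold transcripts. Each gene is therefore represented by its transcript with the highest mean RPKM, which left 11751 genes, and p-values were adjusted by the Benjamini-Hochberg method over all 18577 transcripts. A gene passed at an adjusted p of 0.05. The 3 groups (unmodified, RAD21 line, ATF1 line) were fitted together, with 1 residual degree of freedom from the unmodified pair and a spread that follows the mean level. The prior degrees of freedom came out infinite, so every gene received the spread typical of its level (SD 0.3 to 0.63 on the log2 scale, median 0.41) and its own difference between the unmodified libraries did not enter its test. Each modified line has 1 library, which is assumed to vary as the unmodified ones do; no difference of a line has a replicate check of its own. A second fit took both modified lines together against the unmodified pair, with 2 residual and 11.6 prior degrees of freedom. Its spread therefore includes the difference between the RAD21 and ATF1 lines.

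The same code was tested on simulated data with the levels of the 11751 genes and a spread shared by genes of like level. Every simulated library, also those of the modified lines, had the spread of the unmodified pair. In the RAD21 comparison it recovered 8.4% of genes changed 2-fold, 71.2% of those changed 4-fold and 99.2% of those changed 8-fold, and 4.5% of its calls were false. In the ATF1 comparison it recovered 8.8%, 73.2% and 98.8%, and 5.1% of its calls were false. Because the simulation made the same assumptions as the test, these false shares do not show how often calls in the real libraries are false. Changes were put only into genes with a mean log2 value above 2, so recovery at lower levels was not measured. As a description without a test, genes were also counted whose value lay at least 2-fold from both unmodified libraries on the same side.

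Gene lists for liver functions, cell growth, stress responses, the cohesin complex, the CREB and ATF family and markers of other cells were fixed in advance; 35 lists had at least 3 tested members. A list is described by the number of its members past the threshold and by its median log2 fold change, with the percentile of that median among 10000 random lists of the same size matched on mean expression. The percentile describes these libraries only. The genes named are RAD21, ATF1, CREB1 and GABPA; the 10 genes with the largest change in each direction among those past the threshold and on the same side of both unmodified libraries, filled up with values where fewer passed; and up to 4 members of each list with the largest change. Where another gene is named, the text says that it was chosen after its values were seen.

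Other settings, chosen before the data were examined, were pseudocounts of 0.1 and 0.5, no filter, a minimum mean RPKM of 5, quantile normalization, median-of-ratios scaling, limma without the trend or with robust estimation, a fit on the libraries of the compared groups only, 1 row per gene symbol in the adjustment, and leaving out each library. After the data were seen, 2 more were added: a correction for transcript length, which removed from each library a lowess curve of its deviation from the mean of the 4 libraries on log2 length, and limma's voom on the recovered reads. Tables were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots with matplotlib 3.10.9.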

Results

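Polyadenylated RNA was measured by RNA-seq in 4 libraries of HepG2 cells: 2 of unmodified cells, 1 of the line modified at RAD21 and 1 of the line modified at ATF1. RAD21 is the kleisin subunit of cohesin, the ring complex that holds sister chromatids together and forms chromatin loops. ATF1 is a bZIP transcription factor that binds cAMP response elements together with its relative CREB1. The libraries held between 24029313 and 29972463 mapped reads, and 11475 to 11811 genes had an RPKM of at least 1. Comparing the modified lines with unmodified cells asks how far their transcriptomes differ after tagging, selection and expansion. Each modified line has 1 library, so values of a line carry no SD. Standard errors rest on the spread of the unmodified pair, except where the modified lines were pooled. There the spread also includes the difference between these lines.

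The tagged genes were examined first. RAD21 (NM_006265) had an RPKM of 70.3 ± 7.55 (SD, n = 2) in unmodified cells, 23.9 in the RAD21 line and 50.1 in the ATF1 line. The log2 fold change in the RAD21 line was −1.51 (SE 0.56), and it did not pass the test over all genes (limma, BH-adjusted p = 0.156). Adjusted over the list alone, which held the 4 factors of the study, RAD21 passed. ATF1 (NM_005171) had an RPKM of 4.69 ± 1.08 (SD, n = 2) in unmodified cells, 3.73 in the ATF1 line and 3.40 in the RAD21 line, and its log2 fold change in its own line was −0.25 (SE 0.47). CREB1 stood at 3.15 ± 1.16 RPKM in unmodified cells, 2.93 in the RAD21 line and 2.78 in the ATF1 line. GABPA, an ETS-family factor, stood at 3.69 ± 0.88 RPKM, 2.60 and 3.29. None of ATF1, CREB1 and GABPA passed the test in either line.

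In the RAD21 line, genes of DNA replication and mitosis were lower, and MUC5B, PLG, UGT1A1 and G6PC were among the genes that rose. Of 32 tested genes of DNA replication and mitosis, 19 fell, 13 did not pass and 0 rose, and all 32 lay below both unmodified libraries. Adjusted over the list alone, 31 of them passed. The median log2 fold change of the list was −1.86, at percentile 0.00 of matched random lists, while the difference between the unmodified libraries had a median of 0.32. TOP2A, the topoisomerase that untangles replicated DNA, went from 67.6 ± 26.1 RPKM (SD, n = 2) to 11.7, a log2 fold change of −2.38 (SE 0.55, limma BH-adjusted p = 0.00321). RRM2, a subunit of ribonucleotide reductase, changed by −2.32, the spindle assembly factor TPX2 by −2.22 and cyclin A2 (CCNA2) by −2.20. Other genes among the 10 with the largest falls were MYBL2, a transcription factor of cell cycle genes (−2.71), STMN1, which destabilises microtubules (−2.39), PRR11 (−2.28), the chromatin protein HMGB2 (−2.26), C16orf75 (−2.19) and KIAA1199 (−2.30). For KIAA1199 the unmodified libraries themselves stood far apart, at 22.0 and 5.08 RPKM.

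Of 14 cohesin genes, CDCA5 (sororin, which protects cohesin on replicated DNA) fell by 1.86 on the log2 scale (SE 0.51, limma BH-adjusted p = 0.0199) and the other 13 did not pass. The median of this list was −0.71, at percentile 0.09, and 13 of 14 members lay below both unmodified libraries. SMC3 had a log2 fold change of −0.95 (SE 0.53) and STAG2 of −0.86 (SE 0.51). Among 13 tested replication-dependent histone genes, HIST1H4C (−1.99) and HIST1H1E (−1.51) fell and 11 did not pass. The list as a whole had a positive median of 0.24 (percentile 94.31; 0.71 after a correction for transcript length), with 10 of 13 members above both unmodified libraries, and HIST1H1E no longer passed after that correction (−1.12). HIST1H4C stood at 2.51 and 32.1 RPKM in the unmodified libraries, so its call rests on replicate 2. Because RNA was captured on oligo dT beads, histone values cover mainly polyadenylated transcripts. They need not follow the total transcripts of these genes and are uncertain. Cytosolic ribosomal protein genes had a median of −0.69 and nuclear-encoded respiratory chain genes of −0.78, both at percentile 0.00, with 69 of 77 and 35 of 39 members below both unmodified libraries and 0 past the threshold. RPSA had a log2 fold change of −1.17 (SE 0.65), and ATP5G1 of −1.36 (SE 0.53). These lists also differed between the unmodified libraries, with medians of 0.76 and 0.78 for replicate 2 minus replicate 1. Without unmodified replicate 1 the medians in the RAD21 line were −1.11 and −1.11, and without replicate 2 they were −0.31 and −0.44. They hold short transcripts, and the shortest length class, 43 to 1202 bp, had a median of −0.41 in the RAD21 line. After the length correction their medians were −0.33 and −0.44.

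The largest rise in the RAD21 line was that of MUC5B, a gel-forming mucin, from 2.01 ± 0.30 RPKM (SD, n = 2) to 110.9, a log2 fold change of 5.22 (SE 0.49, limma BH-adjusted p = 3.09e-22). MEP1A, a subunit of the metalloprotease meprin, rose by 2.92 and PLG, which encodes plasminogen, by 2.90. UGT1A1, which conjugates bilirubin, rose by 2.83, LOC100272216 by 2.80 and CRIPAK by 2.70. IGFBP2, an insulin-like growth factor binding protein, rose by 2.68, the dopamine receptor gene DRD4 by 2.68, GSDMB by 2.65 and NPEPL1 by 2.53. IGFBP2 differed widely between the unmodified libraries, at 22.4 and 2.86 RPKM, against 59.9 in the RAD21 line. Of 31 secreted plasma protein genes, PLG and KNG1 (kininogen, 1.62) rose and 29 did not pass. The median of that list was 0.49, at percentile 99.99, and replicate 2 minus replicate 1 of the unmodified cells gave a larger median of 0.77. Without unmodified replicate 1 the median in the RAD21 line was −0.025, and without replicate 2 it was 0.88, so its direction rests on replicate 1. FGB, the fibrinogen beta chain, had a log2 fold change of 1.61 (SE 0.60). Of 15 tested genes of xenobiotic metabolism, UGT1A1, UGT1A6 (2.43), CYP2D6 (1.78) and CYP3A5 (1.45) rose and 11 did not pass. The UGT1A transcripts share their last exons and CYP2D6 has a close pseudogene, so their values are uncertain. Among 19 genes of the cAMP response and immediate early genes, G6PC, the glucose-6-phosphatase of gluconeogenesis, rose from 60.2 ± 12.2 RPKM to 299.7 (log2 fold change 2.31, SE 0.59, limma BH-adjusted p = 0.0103). The other 18 did not pass over all genes, while 4 of the list passed when adjusted over the list alone. PCK1, which catalyses an early step of gluconeogenesis, had a log2 fold change of 1.68 (SE 0.58). SLC22A18, an imprinted transporter gene (1.99), and TPM2, a tropomyosin (2.06), were the members past the threshold in the lists of imprinted genes and of cytoskeletal response.

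In total 270 genes passed in the RAD21 line, 191 higher and 79 lower (limma, BH-adjusted), and all 270 lay outside both unmodified libraries. With no filter on low values 0 genes passed, against 2520 at an unadjusted p under 0.05, and with a minimum RPKM of 5 there were 139. The count was 381 (306 higher, 75 lower) with median-of-ratios scaling, 404 (309 and 95) with quantile normalization and 404 (322 and 82) with the length correction. The median of all genes was −0.13 and moved to −0.009 with median-of-ratios scaling; the directions of the medians for replication and mitosis, cohesin, ribosomal protein, respiratory chain and plasma protein genes were kept under that scaling and under quantile normalization.

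**Figure D1:**
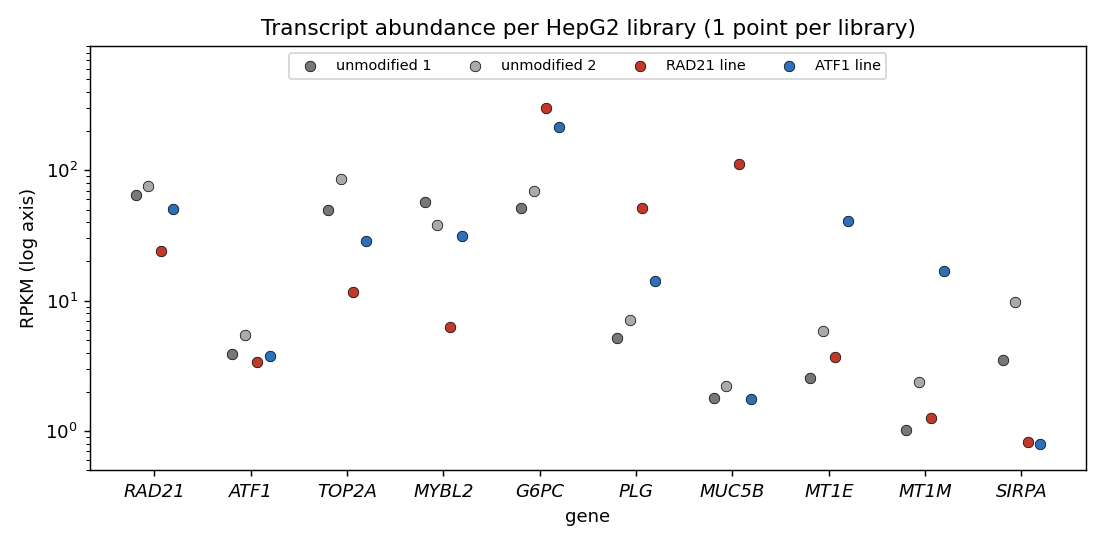
RPKM on a log axis for 10 named genes, with 1 point per library (dark and light grey, unmodified replicates 1 and 2; red, RAD21 line; blue, ATF1 line). MUC5B stands at 110.9 RPKM in the RAD21 line and at 2.22 or less in the other 3 libraries, and MT1E at 40.6 in the ATF1 line and at 5.87 or less elsewhere.

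In the ATF1 line, metallothionein genes rose. These encode small cysteine-rich proteins that bind zinc, copper and cadmium. Of 10 tested genes in the list of metallothioneins and zinc export, 9 rose, 1 did not pass and 0 fell, and all 10 lay above both unmodified libraries. After the length correction 3 of these genes passed and 6 no longer did. MT1E went from 2.53 and 5.87 RPKM in the unmodified libraries to 40.6, a log2 fold change of 3.08 (SE 0.50, limma BH-adjusted p = 2.28e-06). MT1M rose by 2.77, MT1G by 2.73, MT1X by 2.73 and MT1L by 2.68. The zinc exporter SLC30A1 had a log2 fold change of 0.34 (SE 0.51) and did not pass. The median of the list was 2.51, against 0.38 between the unmodified libraries and −0.13 in the RAD21 line. After the length correction it was 1.61 in the ATF1 line and 0.31 in the RAD21 line. Metallothionein transcripts are near-identical copies, so reads could be split among them and the value of each gene is uncertain.

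Of the 19 other genes that rose in the ATF1 line, 12 had transcripts of at most 600 bp. They included RPS29, a protein of the small ribosomal subunit (2.59), MIR1977 (2.50) and the small nucleolar RNA genes SNORA11D and SNORA11E (2.46 each). The last pair had identical values in every library, and these are uncertain. So is the value of the microRNA gene MIR1977, since polyadenylated RNA was captured. Short transcripts as a class were higher in this library: the median log2 fold change was 0.49 for genes of 43 to 1202 bp and −0.30 for genes of 5493 bp or more. Cytosolic ribosomal protein genes had a median of 0.86, at percentile 100 of matched random lists, with 1 of 77 past the threshold; after the length correction that median was 0.23, with quantile normalization 0.56 and without unmodified replicate 1 0.41. RPS21 had a log2 fold change of 2.08 (SE 0.60) without passing. IGFBP2, at 1439 bp, rose by 2.35 (SE 0.53, limma BH-adjusted p = 0.0108), with 22.4 and 2.86 RPKM in the unmodified libraries and 47.5 in the ATF1 line. SIRPA, a cell-surface receptor that binds CD47, was the only gene that fell, by 1.96 on the log2 scale (SE 0.44, limma BH-adjusted p = 0.00908), from 6.61 ± 4.39 RPKM to 0.79.

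Among genes that did not pass, lay below both unmodified libraries and differed by more than these did from each other, the largest negative values were those of AFG3L1 (−1.53), MKI67, a proliferation antigen (−1.34), SLC6A14 (−1.33), C7orf68 (−1.29), ESPL1 (−1.21), C1orf112 (−1.21), RHOBTB1 (−1.20), CENPF (−1.19) and RAD51 (−1.18). The list of DNA replication and mitosis had a median of −0.73, at percentile 0.00, with 28 of 32 members below both unmodified libraries and 0 past the threshold. TOP2A had a log2 fold change of −1.16 (SE 0.55). Cohesin genes had a median of −0.61 (percentile 0.00, 0 of 14 past), or −0.39 after the length correction, with SMC1A at −0.82 and NIPBL at −0.76. Secreted plasma protein genes had a median of 0.59 (percentile 99.92, 0 of 31 past), which was 0.058 without unmodified replicate 1, 1.04 without replicate 2 and 0.32 after the length correction; TTR, which encodes transthyretin, had a log2 fold change of 1.71 (SE 0.59) and APOC1 of 1.76 (SE 0.58). Of the lists of other cells, 5 endothelial markers had a median of 0.75 (percentile 99.82) and 5 blood cell markers of 0.62 (percentile 98.2), with 0 past the threshold in either. The endothelial median differed between the unmodified libraries by −0.87 (replicate 2 minus replicate 1). In the ATF1 line it was 0.90 without unmodified replicate 1, 0.61 without replicate 2, 1.29 with a pseudocount of 0.1 and 1.396 with voom on recovered reads. The median of the blood cell markers was 0.017 without unmodified replicate 1 and 0.35 without replicate 2, and their mean was 0.39. The medians of 9 breast luminal, 3 fibroblast and 6 bile duct markers were 0.41, 0.11 and 0.12. In the RAD21 line the medians of these lists were 0.21, −0.34, −0.40, −0.62 and −0.70 in the same order, with 0 past the threshold. Targets of the antioxidant factor NRF2 had a median of −0.37 in the ATF1 line and heat shock chaperones of −0.43, both at percentile 0.00 and with 0 past the threshold. Without unmodified replicate 1 these medians were −0.088 and −0.60, and without replicate 2 they were −0.54 and −0.30. The mean of the heat shock list was −0.22. AKR1B10 had a log2 fold change of −1.58 (SE 0.55), TXNRD1 of −1.10 (SE 0.55), HSPH1 of −0.87 (SE 0.52) and HSP90AA1 of −0.74 (SE 0.60). AKR1B10 stood at 180.0 and 17.1 RPKM in the unmodified libraries and at 18.1 in the ATF1 line, so its value rests on replicate 1. G6PC was at 216.6 RPKM in the ATF1 line (log2 fold change 1.84, SE 0.59) and did not pass. Its list, cAMP response and immediate early genes, had a median of 0.215 (percentile 93.03) in this line. In the RAD21 line that median was 0.46 (percentile 99.83), and between the unmodified libraries −0.167. The CREB and ATF family with coactivators had medians of −0.125 (percentile 23.02) in the ATF1 line and −0.21 (percentile 44.43) in the RAD21 line.

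In total 29 genes passed in the ATF1 line, 28 higher and 1 lower (limma, BH-adjusted). After the correction for transcript length 10 passed, 6 higher and 4 lower, of which 7 were among the 29; with no filter on low values 0 passed, against 1089 at an unadjusted p under 0.05, with a minimum RPKM of 5 there were 12, and with voom on recovered reads 16.

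**Figure D2:**
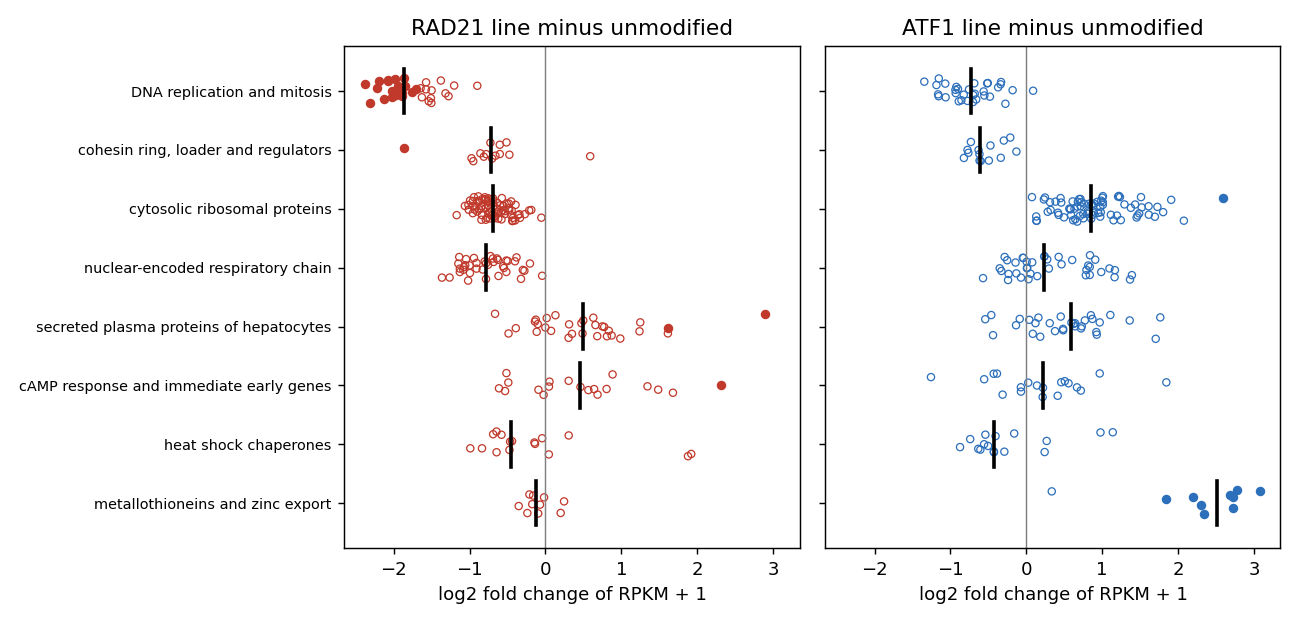
Log2 fold changes of RPKM + 1 for the tested members of 8 gene lists, RAD21 line on the left and ATF1 line on the right. Each point is a gene, filled where it passed the test over all genes; vertical bars are list medians, which are −1.86 and −0.73 for DNA replication and mitosis and −0.13 and 2.51 for metallothioneins.

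The modified lines were also compared with each other, and 137 genes differed, 75 higher in the RAD21 line and 62 higher in the ATF1 line (limma, BH-adjusted). MUC5B differed by a log2 value of 5.35 (SE 0.56), LOC100272216 by 3.58 and CRIPAK by 3.51, all higher in the RAD21 line. FLJ45445 (3.07), LOC440905 (2.97), C2orf14 (2.95), LOC100133161 (2.88), AFG3L1 (2.78), SHISA9 (2.72) and LOC100132062 (2.68) completed the 10 largest. Several of these may belong to copied families, whose reads could be split among the copies. That was not tested, so their values are uncertain. KCNQ1OT1, a long antisense RNA of an imprinted domain, was higher by 2.35 (SE 0.52) and, at 59461 bp, no longer passed after the length correction. Higher in the ATF1 line were MIR1977 (−3.88), MT1E (−3.15), the fatty acid binding protein gene FABP1 (−3.13), MT1X (−3.08), MT1M (−2.98), MT1G (−2.97), MT1L (−2.86), CRIP1 (−2.76), LCN15 (−2.72) and RPS29 (−2.64). The ribosomal protein genes RPS21 (−2.47) and RPL24 (−2.41) and the respiratory chain genes COX7B (−2.11) and NDUFB3 (−1.94) also passed, as did S100A4 (−1.59). The list of DNA replication and mitosis had a median of −1.13, at percentile 0.00, with 0 of 32 past the threshold, so the difference between the lines was not shown for any of its genes. The split of 75 to 62 moved to 135 to 64 with quantile normalization, 121 to 57 with median-of-ratios scaling and 156 to 8 with the length correction. With no filter on low values 0 genes passed, against 2080 at an unadjusted p under 0.05, and with a minimum RPKM of 5 there were 79.

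With both modified lines pooled against unmodified cells, 0 of 11751 genes passed in limma, and voom on recovered reads also gave 0. At an unadjusted p under 0.05 there were 585 genes, a share near 0.05, which unchanged genes alone would give. The spread in this fit includes the difference between the RAD21 and ATF1 lines. Of the 35 lists, 9 had a pooled median outside the central 95% of matched random lists. That of DNA replication and mitosis was −1.25 (percentile 0.00), with 0 of 32 past the threshold. Adjusted over that list alone, 24 of the 32 passed, all lower. Cohesin genes had a pooled median of −0.66 (percentile 0.00, 0 of 14 past) and plasma protein genes of 0.58 (percentile 100, 0 of 31 past). The pooled log2 fold change was 2.55 for MUC5B, which was not higher in the ATF1 line, and 2.52 for IGFBP2, less than the gap between its unmodified libraries. Among genes with both modified lines on the same side of both unmodified libraries and a change larger than the gap between these, the largest positive values were those of MEP1A (2.26), MIR663 (2.17), G6PC (2.08, SE 0.45), PLG (2.00), AGTR1, the angiotensin II receptor gene (1.97), TMEM59L (1.94), UGT1A1 (1.85), OSCAR (1.82), SERPINE2 (1.78) and MMP11 (1.76). By the same rule the largest negative values were those of SIRPA (−1.95, SE 0.41), TOP2A (−1.77), MKI67 (−1.71), SLC6A14 (−1.70), MYBL2 (−1.64), RRM2 (−1.59), NCAPH (−1.57), CCNA2 (−1.55), BUB1 (−1.54) and KIF20A (−1.54). Without the RAD21 line 27 genes passed, and without the ATF1 line 264, which are then the comparisons of the other line alone.

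MIR663, AGTR1 and IGFBP2 rose in both lines and SIRPA fell in both. Independent lists of these lengths would share 0.46 higher and 0.007 lower genes, but these lists are not independent, since they share the unmodified pair. For IGFBP2 the unmodified libraries lay far apart, and its pooled change was less than that gap. The MIR663 value is uncertain, since polyadenylated RNA was captured. The log2 fold changes of the lines correlated across genes with r = 0.26. Simulated unchanged lines that shared a simulated unmodified pair gave 0.33 (0.31 to 0.35 in 100 simulations). Genes are not independent replicates. Every simulated library had the spread of the unmodified pair, whose difference had an SD of 0.563 across genes. The RAD21 line differed from replicates 1 and 2 with SDs of 0.633 and 0.807. A wider spread lowers r, so these r values cannot tell whether changes were shared. The covariance was 0.0779 against a simulated 0.0805, a difference of −0.0026. With a different unmodified library for each line, r was 0.18 in the first arrangement and −0.15 in the other. Since the unmodified pair could not be split with 2 libraries on each side, part of the overlap of calls may come from the shared controls.

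Counted by size alone, 418 genes were at least 2-fold above and 317 at least 2-fold below both unmodified libraries in the RAD21 line, and 157 and 13 in the ATF1 line. In the RAD21 line the split moved to 564 and 225 with median-of-ratios scaling, 524 and 266 with quantile normalization and 555 and 230 with the length correction, and in the ATF1 line to 46 and 18 with the length correction. The unmodified libraries themselves differed at least 2-fold at 881 genes. The RAD21 line differed at 1201 genes from unmodified replicate 1 and at 2539 from replicate 2, and the ATF1 line at 760 and 636. Pearson's r of log2 values over 11751 genes was 0.946 within the unmodified pair, 0.932 and 0.889 for the RAD21 line against replicates 1 and 2, and 0.955 and 0.954 for the ATF1 line. By this measure the ATF1 library was no further from the unmodified libraries than these were from each other.

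**Figure D3:**
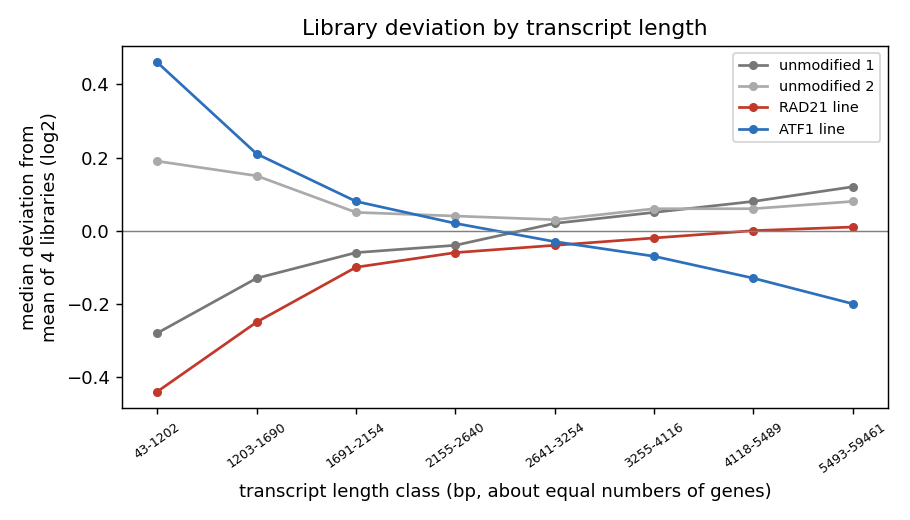
Median deviation of each library from the mean of the 4 libraries (log2 of RPKM + 1) in 8 classes of transcript length in bp, with 1 line per library. In the shortest class, 43 to 1202 bp, the ATF1 line lies at 0.46, unmodified replicate 2 at 0.19, replicate 1 at −0.28 and the RAD21 line at −0.44.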

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

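The test of the difference between the lines singled out 137 genes that differed between the RAD21 and ATF1 lines. Highest in the RAD21 line were MUC5B (log2 difference 5.35), LOC100272216 (3.58) and CRIPAK (3.51), and highest in the ATF1 line MIR1977 (−3.88), MT1E (−3.15) and FABP1 (−3.13). After the length correction the calls of these 3 RAD21-line genes held, and those of MIR1977 (−1.76), MT1E (−1.87) and FABP1 (−1.80) did not. In the tests that follow, the bounds for MALAT1 and NEAT1 were written before their values were seen; the length correction, the whole-library test, the comparison with the ATF1 line, the olfactory receptor test, the length-matched lists and the SLC30A1 test were chosen after the results were seen.

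The fall of replication and mitosis genes in the RAD21 line was weighed first. The list kept a median of −1.71 after the length correction, which argues against transcript length. With median-of-ratios scaling it lay −1.72 from the median of all genes, which argues against a shift of the whole library. The state of this culture, such as slower growth or higher density at harvest, cannot be told apart from an effect of the modified RAD21 gene, because the line has 1 library. The ATF1 line, whose RAD21 gene was not the target, had a median of −0.73, further from 0 than the unmodified pair's own difference of 0.32 but less low than in the RAD21 line. A lower dose of cohesin and clonal selection were not tested, and both stay open. The cohesin list, which does not hold RAD21, was low in both lines, with medians of −0.71 in the RAD21 line and −0.61 in the ATF1 line. Between the lines its median was −0.098 (percentile 43.2), or −0.28 (percentile 3.56) after the length correction. The fall of that list was therefore not particular to the RAD21 line. RAD21 itself stood at 23.9 RPKM in this line, a fall that did not pass over all genes.

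The second pattern was the 191 genes higher in the RAD21 line, 38 of which (19.9%) had noncoding identifiers, against 5.7% of tested genes. Genomic DNA in the library would raise silent genes too. Means of 388 olfactory receptor genes were 0.016 and 0.019 RPKM in unmodified cells, 0.023 in the ATF1 line and 0.045 in the RAD21 line. This background was thus highest in the RAD21 line. Its gain of 0.028 RPKM was 0.30% of the median gain of 9.34 RPKM of the higher genes. That argues against genomic DNA as the source of gains of this size. All 191 genes (100%) still passed after the length correction. The median change in this line was below 0 in every length class, −0.41 to −0.05. The correction therefore raised values and could hardly remove a higher call, so it does not decide on length. A larger share of nuclear RNA in this library is a candidate explanation that met its bound: MALAT1 went from 72.2 and 109.1 to 281.6 RPKM and NEAT1 from 82.7 and 91.2 to 333.3, ratios to the nearer unmodified library of 2.58 and 3.66. Neither gene passed over all genes (limma, BH-adjusted p = 0.13 and 0.0506), and a biological rise of these RNAs in the RAD21 line stays open.

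The third pattern was the genes higher in the ATF1 line. Of the 19 outside the metallothionein list, 3 (15.8%) passed after the length correction, so the bias of this library towards short transcripts may account for most of them. For metallothioneins the median of 2.51 lay above all 10000 random lists matched on length (percentile 100, highest random median 2.05). These lists drew separate genes, while reads could be split among near-identical metallothionein copies. The percentile therefore cannot exclude length as the cause. Length can still have added to their size: after the correction the median was 1.61 and 3 genes passed, MT1E moving from 3.08 to 2.26. Exposure of the culture to metal was left undecided, because SLC30A1, which responds to the same metal-sensing factor, had a log2 fold change of 0.34 with 95% limits of −0.67 and 1.34; an effect of the modified ATF1 gene stays open as well.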

How the results depend on the processing

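Transcript length correction and voom were added after the data were seen; the other settings were planned. The calls depended on the filter: without it 0 genes passed in the RAD21, ATF1 and RAD21-against-ATF1 comparisons. The prior degrees of freedom then fell from infinite to 1.91, so each test had far heavier tails, and the smallest adjusted p was 0.125 for the RAD21 line and 0.302 for the ATF1 line; unadjusted p under 0.05 was reached by 2520, 1089 and 2080 genes. With a minimum mean RPKM of 5 the counts were 139, 12 and 79, with fewer genes tested (8154). The ATF1 count of 29 was 10 after length correction and 16 with voom. Of the 270 and 29 genes, 261 and 7 passed after length correction. The share of higher genes moved from 96.6% to 60.0% for the ATF1 line with length correction, and in the RAD21-against-ATF1 comparison from 54.7% to 67.8% with quantile normalization, 68.0% with median-of-ratios scaling, 41.3% without the trend, 95.1% with length correction and 66.3% with voom. Both lines against unmodified gave 0 genes under all settings that kept the 4 libraries and 0 to 264 when a library was left out, 27 without the RAD21 line and 264 without the ATF1 line. Genes at least 2-fold from both unmodified libraries numbered 735 and 170 in the RAD21 and ATF1 lines, 1129 and 293 with a pseudocount of 0.1, 1201 to 2539 and 636 to 760 when an unmodified library was left out, and 64 in the ATF1 line with length correction. The correlation of the lines' changes, 0.258, was 0.177 and −0.147 with separate unmodified libraries. The cause was not tested unless named.

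Among the named genes, 1404 of 1533 alternative values with a test kept direction and side of the threshold, 83 no longer passed (60 of them with no filter), 39 newly passed and 7 changed sign, all at CREB1 and GABPA: CREB1 in the RAD21 line came to 0.012 with quantile normalization and 0.068 with median-of-ratios scaling; with length correction CREB1 was 0.23 in the ATF1 line, −0.26 between the lines and 0.098 in both, and GABPA 0.093 in the ATF1 line; CREB1 in both ranged from −0.37 without unmodified replicate 1 to 0.21 without replicate 2. In the same order, the medians in the RAD21 line were −0.025 and 0.88 for plasma protein genes (0.49 with both) and −0.32 and 0.72 for cholesterol genes (0.29 with both), and that of respiratory chain genes in the ATF1 line was −0.097 and 0.63 (0.24 with both, percentile 97.77). With length correction the last was −0.058, and that of histone genes in the ATF1 line went from 0.64 (percentile 100) to −0.13. Histone values are uncertain because polyadenylated RNA was captured. Leaving out an unmodified library leaves the single-line comparisons no residual degrees of freedom, so they gave values without a test. Of 156 such values of named genes 4 changed sign: without replicate 2 CREB1 was 0.24 in the RAD21 line and 0.19 in the ATF1 line and GABPA 0.078 in the ATF1 line, and without replicate 1 AKR1B10 in the ATF1 line went from −1.58 to 0.082. No paired analysis was possible because the modified lines have 1 library each and share fewer than 2 replicate numbers with the unmodified cells. Depth limits little here, since 80.1% of genes differed between the unmodified libraries beyond counting error; the number of libraries limits the rest.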

Other observations

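Which lists to describe here was chosen after their values were seen. The unmodified libraries differed from each other in several liver pathways. Genes of cholesterol synthesis and uptake had a median of 1.16 for replicate 2 minus replicate 1, and Wnt and beta-catenin target genes had a median of −0.58. Of the 35 lists, 9 had a median outside the central 95% of matched random lists in this comparison of unmodified cells, against 8 for the RAD21 line and 11 for the ATF1 line.

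In the RAD21 line, genes of fatty acid synthesis had a median of 0.36, at percentile 98.85, with 0 of 16 past the threshold, and of 0.18 without unmodified replicate 1 and 0.58 without replicate 2. SREBF1 had a log2 fold change of 1.43 (SE 0.56) and MLXIPL, the carbohydrate response factor, of 1.52 (SE 0.58). The inducible chaperone genes HSPA1A and HSPA1B had log2 fold changes of 1.92 and 1.88 (limma, BH-adjusted p = 0.0568 and 0.0684), while the list of heat shock chaperones had a median of −0.45; these 2 genes are near-identical, so their values are not separate measurements. Gene families often studied with cohesin were hardly expressed: 4 of 39 HOX genes and 4 of 53 clustered protocadherin genes were tested, and 0 passed. The 4 tested neighbours of RAD21 had a median of −0.44, at percentile 16.13, and the 7 tested neighbours of ATF1 had a median of −0.31 in the ATF1 line, at percentile 5.53.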
